A study of Macaca mulatta with 5 samples.

How the data were processed

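The series held 5 samples: a MeDIP library and a lncRNA library of rhesus monkey embryonic stem cells (rESC), a MeDIP library and a lncRNA library of R_NSCP1 cells, and a MeDIP input mixed from both, which was not analysed here. Groups were taken from the sample titles; the cell type label of all samples reads embryonic stem cell, and the labels do not spell out R_NSCP1. Per the labels' protocols, genomic DNA was sheared and made into libraries before methylated DNA was pulled down with a commercial kit, and total RNA was depleted of ribosomal RNA and made into libraries with a kit that keeps the strand. The submitters' processing notes name BWA 0.7.7, MACS2 and TopHat2 2.0.11.

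Per the file headers, peaks were called with MACS 2.1.0.20150731 on each MeDIP library separately, with no control file, a q cutoff of 0.01, an effective genome size of 3e+09 and at most 1 tag kept per position. Each library was therefore compared with its own regional background over 10000 bp, and not with the mixed input, so copy number and local mappability were not removed by a control. The header values for the fragment length were 249 bp in rESC and 236 bp in R_NSCP1. The pileup signal in the deposited peak lists is the number of fragments stacked at a peak and is not scaled between libraries. The fold enrichment in the deposited peak lists sets that pileup against the local background of the same library, with values that match 1 being added to both terms. The −log10 p and −log10 q values of the deposited peak lists refer to the same background. These values were used to describe, rank and filter peaks within each list. Counts and shares of peaks passing the same threshold were also compared between the lists. In the test of depth the R_NSCP1 threshold of −log10 q was raised by the ratio of tags.

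The lncRNA table gave a position, a strand, an FPKM per library, a p-value and a call for each of 1404 transcripts at 1356 distinct positions. The FPKM values were made by the authors, per the column names, and are not multiples of a step, so no read counts could be recovered and the depth is unknown. How transcripts were assembled, called noncoding and quantified is not given in the sources used here. The p-value column of the authors' deposited table has no stated test. It matched rESC FPKM raised to the truncated R_NSCP1 FPKM, times the exponential of the negative truncated rESC FPKM, over the factorial of the truncated R_NSCP1 FPKM, within 1% for 1404 of 1404 transcripts, which is a Poisson probability only where the rESC FPKM is a whole number. No exact 0 of the table was read as absence of a transcript, and no fold of a single lncRNA is given against a value of 0, although counts and medians of differences include such lncRNAs through the pseudocount.

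The genome build is not given in the sources used here. Both kinds of file use the same chromosome names, and 52 of the 63 sequence names in the lncRNA table also occur in the peak lists, so a shared build was assumed when lncRNA starts were set against peaks. No annotation of that build was used, the files carry no gene names, and the planned counts of genes with a promoter peak, the fixed gene lists and the list of known lncRNAs could not be analysed. Coordinates are 1-based, as in the files.

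Peak lists were compared with bedtools 2.31.1, with an overlap of at least 1 bp counted as shared. The chance level was the mean of 100 circular shifts of the other list within each assembled chromosome by 10% to 90% of its span. Shares carry 95% Wilson intervals. lncRNA differences were R_NSCP1 minus rESC on the log2(FPKM + 0.1) scale, which understates the difference of weakly expressed lncRNAs, among lncRNAs with an FPKM of at least 0.1 in one library or both. Lists of lncRNAs were described by the percentile of their median among 10000 random lists of the same size matched in 5 bins of mean expression. For levels within a single library the random lists were not matched. With 1 library per cell type and assay no test between the cell types was made, and no p-value is given across transcripts. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

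The text names, by a rule fixed before the data were examined, lncRNAs and peaks from among the 10 lncRNAs with the largest difference in each direction among those at an FPKM of at least 1 in the higher library, those among the 5 highest in each library, and for each peak list the 5 longest peaks and the 5 with the highest fold enrichment among unshared peaks. Items outside the rule are said to be so where they appear. Of the peaks and lncRNAs the rule takes, those on unplaced scaffolds are given as counts or without position.

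The steps were tested on simulated data. The overlap step matched a brute-force count in 189 of 189 overlaps, recovered 60.3% where 60.1% of 46073 simulated rESC peaks were planted as shared, and gave 1.08% for unrelated lists against 1.10% for their shifts. For the lncRNA difference beside peaks, with 1395 transcripts, 94% of lists of 80 lowered by 1 on the log2 scale fell below the 2.5th percentile, as did 4% of unchanged lists. Every member was lowered alike, the bins of mean expression were taken before the lowering, and smaller lists were not simulated. For the share of neighbouring lncRNAs with the same sign, over 1093 loci, 4% of shuffled sets and 100% of sets with forced pairs lay above the 97.5th percentile.

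Alternatives fixed before the data were examined covered stricter peak thresholds, merged peaks, other definitions of a shared peak, other pseudocounts, filters and fold thresholds for lncRNAs, and a wider window of 5000 bp around lncRNA starts. They also covered lncRNA differences centred on their median. Further alternatives were added after the data were seen and are named as such in the closing section.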

Results

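DNA methylation and long noncoding RNA (lncRNA) were measured in rhesus monkey (Macaca mulatta) embryonic stem cells, labelled rESC, and in cells labelled R_NSCP1. The series concerns how noncoding RNA and DNA methylation act when embryonic stem cells take a neural fate, so R_NSCP1 was set against rESC throughout. Methylation was measured by MeDIP-seq, in which an antibody pulls down sheared methylated DNA that is then sequenced, and lncRNA by sequencing of RNA freed of ribosomal RNA. Each cell type had 1 MeDIP library and 1 lncRNA library, and 1 further sample, an input mixed from both cell types, was not analysed here. There were therefore no replicates, and every difference given is a difference between 2 libraries, with intervals that cover counting error only. The rESC MeDIP library held 8690541 tags and the R_NSCP1 MeDIP library 9071243 tags, a ratio of 1.04. The lncRNA table listed 1404 transcripts by position, and the depth behind its FPKM values (fragments per kilobase of transcript, scaled to the size of the library) is unknown.

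More MeDIP peaks were called in R_NSCP1 than in rESC. The R_NSCP1 list held 83528 peaks covering 26.7 Mb and the rESC list 48838 peaks covering 16.4 Mb, so that R_NSCP1 had 71.0% more peaks. The peaks were of like size, with a median length of 277 bp in R_NSCP1 and 287 bp in rESC. The excess was present on the assembled chromosomes, where 79889 peaks stood against 46073, and was smaller on unplaced scaffolds, where 3631 stood against 2758, a ratio of 1.32. It was also present among the peaks with the strongest statistical support: at a −log10 q of at least 10 the counts were 25563 and 12108, at 20 they were 5565 and 3303, and at 50 they were 755 and 532. The ratio moved with the threshold without a steady trend: it was 1.71 over all peaks, 1.78 at a −log10 q of at least 5, 2.11 at 10, 1.68 at 20 and 1.42 at 50. The q values come from the authors' peak caller, which took the background of each library from that library itself.

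Most rESC peaks were also called in R_NSCP1, whereas most R_NSCP1 peaks had no counterpart in rESC. Of the rESC peaks, 33115 or 67.8% (95% Wilson interval 67.4% to 68.2%) overlapped an R_NSCP1 peak by at least 1 bp. Of the R_NSCP1 peaks, 33119 or 39.7% (39.3% to 40.0%) overlapped an rESC peak, which left 50409 R_NSCP1 peaks and 15723 rESC peaks without a partner. On the assembled chromosomes, shifting the other list along each chromosome gave an overlap of 1.76% ± 0.06 (SD, 100 shifts) for rESC peaks and 1.03% ± 0.04 for R_NSCP1 peaks, so the lists overlapped 38.1 and 37.8 times as often as shifted lists. The difference between these shares follows from the lengths of the lists, since nearly equal numbers of peaks overlapped: with the 48838 strongest peaks of each library, 53.9% of rESC peaks and 53.5% of R_NSCP1 peaks had a partner.

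Sharing depended on how strong a peak was within its own list. Among rESC peaks, 41.7% of the weakest 10% by −log10 q and 99.3% of the strongest 10% overlapped an R_NSCP1 peak, and 35 of the 4884 strongest lacked one. Among R_NSCP1 peaks the share ran from 16.7% in the weakest 10% to 93.3% in the strongest, where 559 of 8353 lacked an rESC peak. At a −log10 q of at least 20, 146 R_NSCP1 peaks and 9 rESC peaks had no partner, and 126 of the 146 lay on assembled chromosomes. Unshared peaks lay less often in the outermost 5% at either end of a chromosome than shared ones: 14.7% (14.1% to 15.3%) of rESC peaks without a partner and 18.5% (18.2% to 18.9%) of R_NSCP1 peaks without a partner lay there, against 24.9% (24.4% to 25.3%) of shared rESC peaks.

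**Figure D1:**
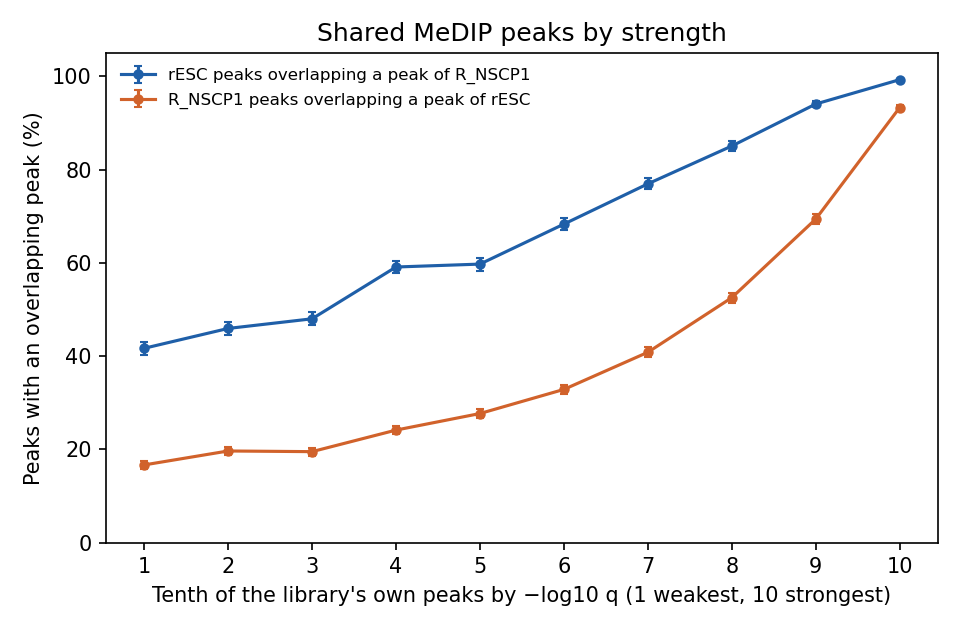
Share of MeDIP peaks that overlapped a peak of the other library (vertical axis, percent) against the position of the peak in its own list, cut by −log10 q into 10 parts of equal size (horizontal axis, 1 weakest to 10 strongest), with 95% Wilson intervals that cover counting error only. The share ran from 41.7% to 99.3% for rESC peaks (blue) and from 16.7% to 93.3% for R_NSCP1 peaks (orange).

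The excess in R_NSCP1 was found on every assembled chromosome and was smallest on the X chromosome. Chromosome X held 1807 rESC and 2731 R_NSCP1 peaks, a ratio of 1.51 (1.42 to 1.60, 95% exact binomial interval of the counts). The autosomes together held 44266 and 77158 peaks, a ratio of 1.74, and single autosomes ranged from 1.61 (1.53 to 1.70) on chromosome 5 to 1.86 (1.75 to 1.97) on chromosome 20. The interval of chromosome X overlapped that of chromosome 5. In windows of 1 Mb with at least 10 peaks over both libraries, R_NSCP1 had more peaks in 2708 of 2813 windows, rESC in 56, and 49 were equal. The windows with the largest surplus of unshared R_NSCP1 peaks, chosen after their values were seen, lay at or near chromosome ends: bases 1 to 1000000 of chromosome 19, with 57 rESC and 112 R_NSCP1 peaks, bases 1000001 to 2000000 of chromosome 15, with 48 and 102, and bases 73000001 to 74000000 of chromosome 18, with 65 and 119. Ranking by the number of peaks favours windows dense in peaks, so these windows do not show a larger excess at chromosome ends. Of the unshared R_NSCP1 peaks, 18.5% lay in the outermost 5% at either end, against 24.8% of shared R_NSCP1 peaks.

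**Figure D2:**
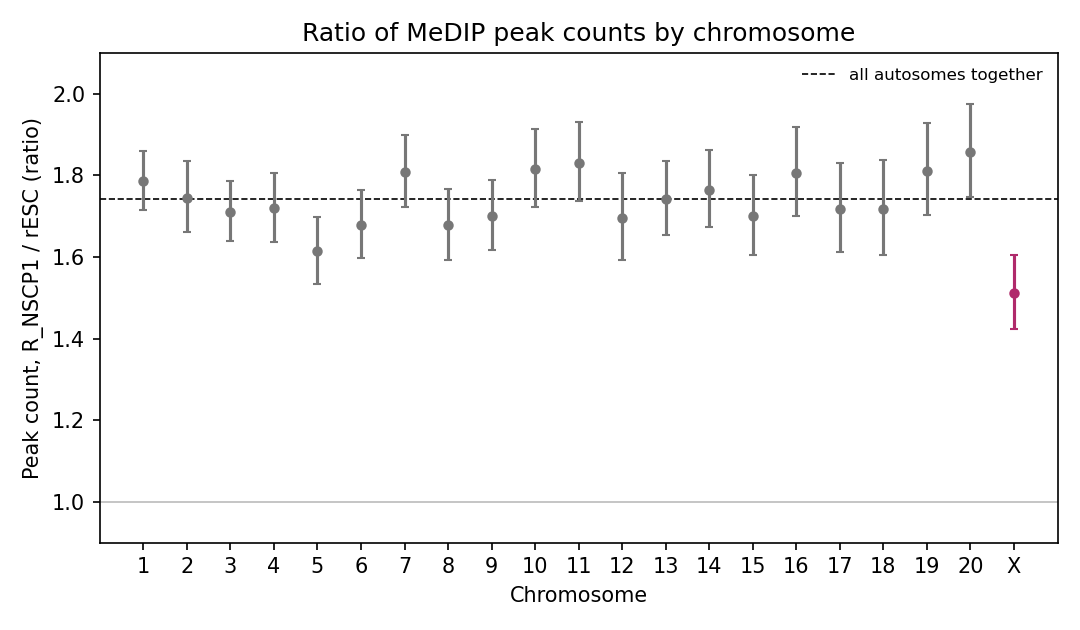
Ratio of the number of R_NSCP1 peaks to rESC peaks (vertical axis) on each chromosome (horizontal axis), with 95% exact binomial intervals of the counts; the dashed line marks the autosomes together, at 1.74, and the grey line a ratio of 1. Every chromosome lay above 1, from 1.51 on X to 1.86 on chromosome 20.

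The longest MeDIP peaks lay at places called in both cell types. With no control in the peak calls, copy number and local mappability can also give such shared peaks, so they are not shown to be methylated. Peaks were also called on chromosome M, 7 in rESC and 8 in R_NSCP1, with −log10 q of up to 69.6 and 47.8. The longest rESC peak spanned 2180 bp on chromosome 15 from 109018790 to 109020969, and the longest R_NSCP1 peak spanned 2192 bp at the same place, from 109018774 to 109020965. Peaks of 1976 bp in rESC and 1943 bp in R_NSCP1 covered chromosome 2 from 113049613 to 113051588, and peaks of 1991 bp and 1966 bp covered chromosome X from 94179072 to 94181062. The second-longest R_NSCP1 peak, 2094 bp on chromosome 2 from 41180769 to 41182862, overlapped a shorter rESC peak of 1748 bp. All 5 of the longest peaks of each library overlapped a peak of the other.

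In rESC the highest fold enrichment over local background among unshared peaks, 17.9, belonged to a peak of 298 bp on chromosome 14 from 125170576 to 125170873, followed on assembled chromosomes by a peak on chromosome 4 from 144364922 to 144365238 (12.7) and a peak on chromosome 13 from 37209963 to 37210344 (11.9). In R_NSCP1 the 5 unshared peaks with the highest fold enrichment, each at least 19.5, all lay on unplaced scaffolds. On assembled chromosomes the highest R_NSCP1 values, looked up after this was seen, were 15.6 on chromosome 14 from 96779243 to 96779628, 14.4 on chromosome 13 from 103551752 to 103552097 and 14.2 on chromosome 12 from 42786749 to 42787071. Fold enrichments are the authors' and rank peaks within a list only. The genome build is not given in the sources used here, so these positions were not assigned to genes.

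Many listed lncRNAs differed in FPKM between the libraries, with no replicate spread to set this against. Of the 1404 listed transcripts, 47 stood under an FPKM of 1 in both libraries. How transcripts were chosen for the list is unknown. A choice by level in either library can lower the correlation between libraries and raise the shares that differ. At an FPKM of at least 0.1, 1204 lncRNAs were detected in rESC, 1294 in R_NSCP1 and 1103 in both. Of 1395 lncRNAs detected in at least 1 library, 484 (34.7%, Wilson interval 32.2% to 37.2%) were at least 2-fold higher in R_NSCP1 on the log2(FPKM + 0.1) scale, 429 (30.8%, 28.4% to 33.2%) were at least 2-fold higher in rESC, and 482 lay within 2-fold. Leaving out lncRNAs listed at 0 in either library, a filter added after the data were seen, left 336 higher in R_NSCP1 and 363 in rESC. By construction this filter takes more from the R_NSCP1 side, since 156 lncRNAs were listed at 0 in rESC and 70 in R_NSCP1. It therefore does not show what the surplus rests on. The median difference, R_NSCP1 minus rESC, was 0.09. Across the 1103 lncRNAs detected in both, the log2 values of the libraries correlated with a Pearson r of 0.403 and a Spearman rho of 0.302, across transcripts, which are not independent replicates; over all 1395 the values were 0.0793 and 0.108.

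The direction of the difference went with abundance, in splits chosen after the data were seen. These splits use the same values whose difference is counted. FPKM values also spread more widely in rESC (quartiles 0.69 to 5.10) than in R_NSCP1 (1.22 to 4.31). Unequal spread between libraries of unknown depth can give such a pattern, so the splits cannot show that direction depends on abundance. In 5 groups of 279 lncRNAs ordered by the mean FPKM of both libraries, 165 were higher in R_NSCP1 and 70 in rESC in the lowest group, and 46 and 130 in the highest. Among the 204 lncRNAs with an FPKM of at least 10 in one library or both, 113 (55.4%, 48.5% to 62.1%) were higher in rESC and 42 (20.6%, 15.6% to 26.7%) in R_NSCP1, the opposite of the split over all lncRNAs. There were 157 lncRNAs that reached an FPKM of 10 in rESC and 103 in R_NSCP1, and the FPKM values summed to 11141 and 8895. More lncRNAs were listed at 0 in rESC, 156 against 70 in R_NSCP1. Of those at an FPKM of at least 1 in the other library, 136 were listed at 0 in rESC and 61 in R_NSCP1. On the X chromosome 27 lncRNAs were higher in rESC and 17 in R_NSCP1, and on the autosomes 383 and 456.

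**Figure D3:**
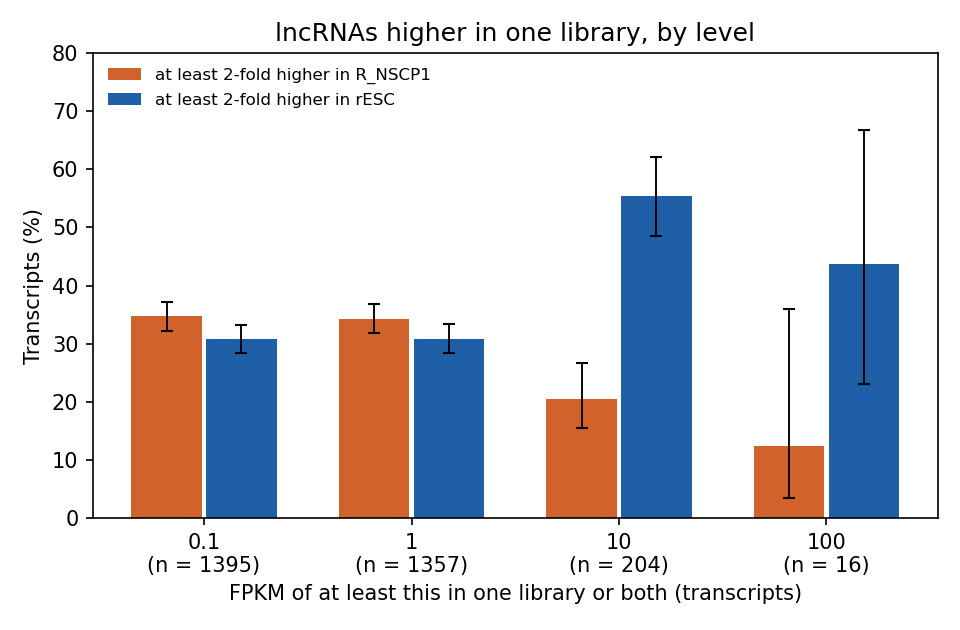
Share of lncRNAs at least 2-fold higher in R_NSCP1 (orange) or in rESC (blue) on the log2(FPKM + 0.1) scale (vertical axis, percent), among lncRNAs whose FPKM reached 0.1, 1, 10 or 100 in one library or both (horizontal axis, with the number of transcripts); bars carry 95% Wilson intervals that cover counting error only. From an FPKM of 10 the larger share was higher in rESC, 55.4% against 20.6%; at 100 only 16 transcripts were left.

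The largest differences towards R_NSCP1 were those of abundant lncRNAs listed at 0 in rESC. A lncRNA on the minus strand of chromosome 4 from 67718180 to 67719576 stood at an FPKM of 922.8 in R_NSCP1, the second-highest value of that library, and at 0 in rESC. Others listed at 0 in rESC lay on chromosome 5 from 60164514 to 60165039 (FPKM 128.9 in R_NSCP1), chromosome 1 from 172181008 to 172218215 (45.4), chromosome 6 from 85073518 to 85117784 (13.9), chromosome 10 from 43431506 to 43580379 (12.4), chromosome 7 from 14327957 to 14329504 (11.1) and chromosome 14 from 30721113 to 30852788 (10.9). A transcript on chromosome 11 from 24616623 to 24782876 was listed at 0 and 22.6, but a second transcript with the same ends stood at 11.8 in rESC and 37.9 in R_NSCP1. With a value above 0 in both libraries, a lncRNA on chromosome 8 from 68783962 to 68789729 went from 0.107 in rESC to 24.2 in R_NSCP1, a log2 difference of 6.88, and a lncRNA on chromosome 2 from 106613376 to 106688854 from 0.012 to 13.2, a log2 difference of 6.89. These sizes depended on the pseudocount: with pseudocounts of 1 and 0.01 the differences were 4.51 and 7.69 on chromosome 8 and 3.81 and 9.23 on chromosome 2.

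Towards rESC, the lncRNAs with the largest differences and listed at 0 in R_NSCP1 lay on chromosome 6 from 112592294 to 112593576 (FPKM 93.7 in rESC), chromosome 18 from 5466214 to 5470679 (63.0), chromosome 4 from 29216414 to 29231544 (59.6), chromosome 20 from 3236948 to 3244236 (48.4), chromosome 2 from 146392698 to 146414019 (35.3), chromosome X from 36079603 to 36097981 (18.8), chromosome 13 from 110608301 to 110641355 (14.2) and chromosome 12 from 70751782 to 70765512 (13.2). A lncRNA on chromosome 3 from 48932548 to 48937037 stood at 28.1 in rESC and 0.0365 in R_NSCP1, a log2 difference of -7.69, and one on chromosome 2 from 161536533 to 161540528 at 25.6 and 0.0396, a log2 difference of -7.52. With a pseudocount of 1 these differences were -4.81 and -4.68. Overlapping transcripts of the same strand were listed at 4 of these 10 places. They were also lower in R_NSCP1 on chromosomes 20, X and 13, where on chromosome 13 they kept FPKM values of 2.69 to 6.35. On chromosome 3 one of them stood at 70.2 in rESC and 0.436 in R_NSCP1, and another, near the floor, at 0.0717 and 0.383.

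Apart from the lncRNA of chromosome 4 at 922.8, listed at 0 in rESC, the lncRNAs among the 5 highest of either library had values above 0 in both cell types. The highest rESC value, 1203, belonged to a short transcript of an unplaced scaffold that stood at 514.9 in R_NSCP1. A lncRNA on chromosome 14 from 9171966 to 9182049 had the highest R_NSCP1 value, 947.6, against 494.7 in rESC, a log2 difference of 0.94. A second transcript with the same ends stood at 0.0967 in rESC and 16.8 in R_NSCP1. A lncRNA on chromosome 11 from 53371688 to 53372961 stood at 634.1 in rESC and 362.3 in R_NSCP1, and a lncRNA on chromosome 9 from 47093116 to 47095917 at 205.3 and 113.0. One on chromosome 4 from 105191041 to 105193609 differed more, with 196.2 in rESC and 19.7 in R_NSCP1, a log2 difference of -3.31.

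The authors' deposited table called 224 lncRNAs up and 127 down in R_NSCP1. Of the 224 up calls of the authors' deposited table, 60.7% carried a p-value of 0, and all of these 136 were listed at an FPKM of 0 in rESC. Of the 61 lncRNAs listed at 0 in R_NSCP1 with an FPKM of at least 1 in rESC, the authors' deposited table called 25. The p-values of the authors' deposited table equalled, within 1% for 1404 of 1404 transcripts, an expression of the Poisson form computed on FPKM values, partly truncated to whole numbers, with rESC in the place of the mean. Such p-values carry no information on replicate spread. Of the calls in the authors' deposited table, 223 up and 122 down differed by at least 2-fold on the log2(FPKM + 0.1) scale.

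Whether lncRNA levels differed where a MeDIP peak was called in only 1 library was asked at the lncRNA starts. A MeDIP peak lay within 1000 bp of the start of 60 of the 1395 lncRNAs in both cell types, of 78 in R_NSCP1 only and of 15 in rESC only. lncRNAs with a peak in R_NSCP1 only had a median log2 difference of -0.20, which lay at percentile 17.2 of 10000 random lists matched on mean expression (central 95% -0.48 to 0.71): 25 were higher in rESC and 21 in R_NSCP1. Those with a peak in rESC only had a median of 0.05 (percentile 51.8), and those with a peak in both a median of 0.52 (percentile 89.9). None of these 3 lists stood outside the central 95% of its random lists. Starts were near a peak somewhat more often than shifted positions: 9.44% in R_NSCP1 against 6.21% ± 0.81 (SD, 100 shifts), and 4.98% in rESC against 3.53% ± 0.55, where the highest single shift, 5.06%, lay above the observed share.

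Single lncRNAs with a peak near the start in R_NSCP1 only went both ways; these examples were chosen after their values were seen. The lncRNAs on chromosome 2 from 146392698 to 146414019 and on chromosome X from 36079603 to 36097981, both listed at 0 in R_NSCP1, had such a peak, from 146413219 to 146413458 and from 36078750 to 36078998. So did a lncRNA on chromosome 2 from 106544160 to 106547048, which stood at 0.0717 in rESC and 9.53 in R_NSCP1 and had a peak from 106547707 to 106547947.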

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

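Some settings were chosen only after the data were seen. For peaks, they are the −log10 q of at least 20 and, for shares, the restriction to chromosomes 1 to 20 and X. For lncRNAs, they are the forms of list other than the planned pseudocounts, filters, centring on the median difference and 4-fold threshold. The swapped roles and summed FPKM in the authors' calls and all settings for neighbouring lncRNAs were also chosen then. R_NSCP1 had more peaks in each setting run for the peak counts, and the share of rESC peaks with a partner was the larger one in each setting run for the shares, by little with lists of equal length. At a −log10 q of at least 20 the counts were 3303 and 5565. The share of rESC peaks with a partner, and that of R_NSCP1 peaks, was 65.6% and 37.8% when at least 50% of the peak had to overlap, 63.0% and 36.8% with a reciprocal overlap of 50%, 66.6% and 38.2% at a fold enrichment of at least 5, 69.7% and 41.7% when a peak within 500 bp counted, 67.3% and 38.8% on chromosomes 1 to 20 and X, and 53.9% and 53.5% with lists of equal length; at a −log10 q of at least 5 the rESC share was 70.0%. More lncRNAs were higher in R_NSCP1 than in rESC in each planned setting, with 315 and 261 at 4-fold, but the order turned to 42 and 113 at an FPKM of at least 10 and to 22 and 75 at a mean FPKM of at least 10; the cause was not tested. It also turned, to 336 and 363, for FPKM above 0 in both libraries, by construction, since that leaves out the lncRNAs listed at 0, more of them in rESC. The order held in the other settings added after the data were seen. These gave 469 and 408 with 1 transcript per position, and 399 and 328 with FPKM summed over overlapping transcripts. In the authors' deposited table, swapping the roles of the libraries in the p-value gave 48 calls up and 222 down, requiring both roles gave 48 up and 127 down, and summing FPKM over overlapping transcripts gave 175 up and 113 down. The share of neighbouring lncRNAs with the same sign was 84.5% at gaps of at most 10 kb and 57.0% at gaps of 100 kb to 1 Mb, against 73.7% at up to 100 kb. The median difference of lncRNAs with a start peak in rESC only was 0.05 over 15 lncRNAs, -0.20 over the 57 with a peak within 5000 bp and -0.15 over the 12 left at a −log10 q of at least 5; with a peak in R_NSCP1 only it was -0.20 over 78 lncRNAs and -0.06 over the 236 with a peak within 5000 bp. The size of the differences of the 20 lncRNAs named for them moved with the pseudocount, which cannot change their direction. The planned counts of genes with a promoter peak and their alternatives were not run, since no annotation of the build was used. No paired analysis was possible because each group held 1 library and no result came from a test across libraries. With 1 library per cell type, depth and the lack of replicates limit every value to these libraries.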

Other observations

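The tests of depth, immunoprecipitation strength and chromosome copies, the correlation over chromosomes, the calls on summed FPKM, the medians within each library and on chromosome X, and the gap settings for neighbouring lncRNAs were chosen only after the results they bear on, or closely related ones, were seen; the other tests were written down before their outcome was seen.

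lncRNAs lying close together often differed in the same direction; the clusters named here were chosen after their values were seen. On chromosome 7 from 164721815 to 164877311, 9 successive lncRNAs, 8 on the plus strand and 1 on the minus strand, were all higher in R_NSCP1; 8 had log2 differences from 1.06 to 2.33, 1 was listed at 0 in rESC and at 4.76 in R_NSCP1, and the last of them stood at an FPKM of 4.09 in rESC and 12.8 in R_NSCP1. On chromosome 2 from 106544160 to 106841517, 4 lncRNAs stood at 0.0717 or below in rESC and at 3.48 to 13.2 in R_NSCP1. On chromosome 4 from 27989233 to 28200041, 5 lncRNAs were higher in R_NSCP1, with log2 differences from 0.65 to 2.43. The other way, 3 lncRNAs on chromosome 12 from 47328089 to 47684096 were higher in rESC, at 44.7, 16.9 and 12.1 against 5.91, 3.24 and 0.505, and 3 on chromosome 11 from 107141202 to 107152626 were higher in rESC, the most abundant at 167.0 against 29.6.

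Over the whole table, 126 of 171 neighbouring pairs with a gap of at most 100 kb, taking 1 transcript per place, had the same sign, 73.7% (Wilson interval 66.6% to 79.7%), whereas 10000 shuffles of the differences gave a central 95% of 42.7% to 57.9%. Successive pairs share members, so this interval is too narrow. The shuffles did not keep the level of expression, although direction went with level in the splits by mean FPKM. The share was 84.5% at gaps of at most 10 kb and 57.0% at 100 kb to 1 Mb. Pieces of a single transcription unit listed as several lncRNAs need share a direction only on the same strand. Pairs on opposite strands shared it in 76.1% of 67 pairs (shuffles 38.8% to 62.7%). Pairs on the same strand shared it in 72.1% of 104 pairs (shuffles 40.4% to 59.6%). This argues against pieces as the whole cause, provided that reads were assigned to the right strand. Regulation shared by neighbouring lncRNAs in the change between the cell types remains a hypothesis from 1 library of each cell type and was not tested. Reads assigned to the wrong strand and shared read mapping were not tested and stay open.

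R_NSCP1 had more MeDIP peaks than rESC. Sequencing depth is argued against, because with the R_NSCP1 threshold raised by the ratio of tags, 5100 R_NSCP1 peaks still stood against 3303 rESC peaks at a −log10 q of at least 20, a ratio of 1.54. Extra copies of single chromosomes are argued against by the lowest ratio of any assembled chromosome, 1.51 on X. A stronger immunoprecipitation in R_NSCP1 would keep the strong rESC peaks, and only 0.717% of the strongest 10% of rESC peaks lacked an R_NSCP1 peak. The excess was not limited to weak peaks. The ratio of peak counts was 1.71 over all peaks, 2.11 at a −log10 q of at least 10, 1.68 at 20 and 1.42 at 50. At 20, 146 R_NSCP1 against 9 rESC peaks were unshared. A stronger immunoprecipitation could raise −log10 q at every site, so these values do not count against it. Immunoprecipitation strength and a methylation difference between the cell types, which is untested, therefore cannot be told apart, because each cell type had 1 immunoprecipitation and no control entered the peak calls.

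The authors' deposited table held more up than down calls. With the roles of the libraries swapped in its p-value and the same threshold, 222 lncRNAs were called down and 48 up. This was 4.62 down for each up. The direction of the excess in the authors' deposited table therefore turned on which library stood as the mean. At an rESC FPKM of 0 the formula gives a p-value of 0 for any R_NSCP1 FPKM of at least 1. All 136 such lncRNAs were called up, the lowest at 1.11. At 0 in R_NSCP1, the lowest rESC FPKM called was 7.01. Of the up calls, 88 had an rESC FPKM above 0, against 127 down calls, 25 of them at 0 in R_NSCP1. Abundance moved between overlapping listed transcripts is argued against as the whole cause. With FPKM summed over them, 175 calls up still stood against 113 down, a ratio of 1.55 (exact binomial interval 1.22 to 1.98). The summed calls used the same formula, so this ratio still carries its asymmetry and says nothing about other causes. Only 42 of the 136 lncRNAs overlapped any listed transcript of the same strand, so summing could not change the others. Of the lncRNAs listed at 0 in rESC and at an FPKM of at least 1 in R_NSCP1, 16.9% (23 of 136, Wilson interval 11.5% to 24.1%) overlapped a transcript of the same strand at an FPKM of at least 1 in rESC, and in the opposite direction it was 23.0% (14 of 61, 14.2% to 34.9%), so a part in single calls stays open in both directions. The excess of up calls is therefore no evidence that more lncRNAs rose than fell, and a difference between the cell types stays open and untested.

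Lower expression where only R_NSCP1 had a peak near the lncRNA start was not seen clearly. The median difference lay at percentile 17.2 of matched random lists, which neither excludes nor shows it. Simulated lists of 80 lowered by 1 on the log2 scale passed the limit in 94% of runs. Every member was lowered alike and the expression bins were taken before the lowering. This share therefore does not tell how often a real drop would be found. Within each library, lncRNAs with a start peak had a median FPKM of 2.22 against 2.35 in rESC and 2.40 against 2.52 in R_NSCP1. These medians lay at percentiles 37.0 and 26.4 of random lists of the same size that were not matched on expression. The 75 lncRNAs of chromosome X had a median difference of -0.40, at percentile 18.1 of random lists matched on mean expression.

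Autosomes denser in rESC peaks had a larger ratio of R_NSCP1 to rESC peaks. Over the 20 autosomes Pearson's r was 0.545 (two-sided permutation p = 0.0125, adjusted 0.0250) and Spearman's rho was 0.450 (permutation p = 0.0489, adjusted 0.0489). The adjustment covers these 2 coefficients of a single relation, and not the choice of that relation after related results were seen. The rESC peak count enters both the density and the ratio. Without chromosomes 19 and 10, the farthest from the median density, r was 0.440 (permutation p = 0.0685), so the relation rests in part on those 2 chromosomes. The correlation is over chromosomes of 1 library pair, not over samples.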
